A study of Mus musculus with 264 samples.

How the data were processed

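Messenger RNA was measured in 264 single neurospheres, which are free-floating aggregates of neural progenitor cells. They were grown from the dorsal telencephalon of C57/Bl6 mouse fetuses at gestational day 12.5. The groups were 0 mM ethanol with 68 neurospheres, 25 mM with 64, 70 mM with 66 and 100 mM with 66, taken from each neurosphere's ethanol label. Cultures came in 2 sets, Set-A and Set-B, with 132 neurospheres each, and were measured in 3 runs of 88. The series design names 400 neurospheres, 200 per set, and the others are not analysed here. Run 1 held both sets, run 2 held Set-A and run 3 held Set-B, which makes 4 combinations of run and set. The sources name the doses differently: the sample labels give 25, 70 and 100 mM, the series design 25, 75 and 100 mM, and the treatment protocol 26, 70 and 100 mM. The sample labels were followed. The stage label counts upward from sample to sample, so the stage was taken from the source description.

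Per the labels' protocols, each neurosphere was imaged, lysed, reverse transcribed and pre-amplified without RNA extraction, then read on Biomark HD microfluidic arrays with EvaGreen dye over 30 amplification cycles. The deposited values are quantification cycle (Ct) numbers calculated by the instrument's software per the labels, not normalized per the file headers. A cycle number is an inverted log2 scale: product that appears 1 cycle earlier came from about 1 doubling more template, if every primer pair doubles its product in each cycle. Primer efficiency, software version and the rule behind missing values are not given in the sources used here. The table held 75 assays under coded identifiers, and the series design names 96 genes; the others are not analysed here. The files do not pair the identifiers with genes, and 0 of 75 matched the gene name table for mouse (assembly GRCm38.p6). Cycle numbers ran from 2.5 to 28.78. Of 19800 values, 2055 (10.4%) were missing and were read as not detected. There is no count of molecules behind a cycle number, so precision was taken from the spread between neurospheres.

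Each neurosphere was centred on its mean cycle number over the 50 assays detected in at least 95% of neurospheres, and the sign was turned so that higher means more. These values are called relative levels, in log2 units. The 72 assays detected in at least 50% of neurospheres were tested and 3 were left out. A quality filter asked for at least 34.5 detected assays and removed 0 neurospheres, since the fewest detected was 47. Levels were tested with limma 3.58.1 in R 4.3.3, with the 4 combinations of run and set as a covariate, all 4 dose groups in the fit and Benjamini-Hochberg adjustment over the assays tested at 0.05. Interactions were tested with a moderated F test. Detection was tested with the exact conditional Mantel-Haenszel test, two-sided, over assays detected in 5% to 95% of neurospheres. Diameter, mean cycle number and principal component scores were tested with two-sided permutation tests of 100000 resamples, with dose labels permuted within run and set and adjustment over the 3 doses. Differences between the sets were adjusted over 12 tests, the 3 doses for diameter, mean cycle number, component score and the spread of that score, which was added after seeing the data; the smallest p they can give is 1e-05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

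Because no assay has a gene name, the gene list scores, the maturation score and every normalization to reference genes that were fixed before the data were examined could not be computed. The rule for named assays took up to 20 per ethanol comparison with adjusted p under 0.05, the same direction in both culture sets and the largest change. It was narrowed to 2 assays that rose and 2 that fell at 100 mM, A025, A058, A045 and A009, which are followed through the other doses.

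The tests were checked on simulated data for 100 mM against 0 mM, with dose labels shuffled within run and set and changes added to 24 of 72 assays in 50 simulations. The level test recovered 32.3% of added log2 changes of 0.5, 79.0% of 1 and 98.3% of 2, with 0.6 false calls per simulation. These changes were added after centring, as many up as down, and the shuffling removed any difference in mean cycle number. The simulations therefore cannot show false calls that centring makes where mean cycle number differs between doses. The dose by culture set test recovered 4.75% of changes of 0.5 placed in Set-B alone, 22.8% of 1 and 75.5% of 2. The detection test, on 25 assays in 20 simulations, recovered 93.1% of assays that lost detected values. Each detected value of those assays at 100 mM was removed with a probability of 0.5, and smaller losses were not tried. The permutation test on mean cycle number gave p under 0.05 in 5.0% of 60 simulations without an effect. That rate follows from shuffling within the same run and set as the test, and it says nothing about differences between cultures. No pair of neurospheres shared over 50% of its values.

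Alternatives were other normalizations, other treatments of missing values, other detection filters, a rank scale, added covariates, fits within 1 run or 1 culture set, and a fit of 8 means, 1 per culture set and dose. In the fit of 8 means, a mean needed values in both runs of its set. A045, which was not detected in run 3, had no Set-B mean there. The labels name the set of each neurosphere and no culture within a set. Per the labels' growth protocol the neurospheres came from 6 isolations of 12 pregnancies, which are not tied to single neurospheres. P-values over neurospheres therefore measure the spread between neurospheres and not between cultures, and each of the 8 means may pool several cultures.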

Results

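Single neurospheres exposed to 0, 25, 70 or 100 mM ethanol were compared for the level of 75 assayed transcripts, for the share of neurospheres in which each was detected, and for neurosphere diameter. The series asks whether ethanol shifts the molecular state of neurospheres. A neurosphere had a median of 69 detected assays, with a range from 47 to 74, and 18 assays were detected in all 264 neurospheres. The assays carry codes without gene names, so transcripts are described by number and direction. Each dose was given in 2 culture sets only, so p-values measure the spread between neurospheres and are too small as statements about cultures. The 3 comparisons with 0 mM share the same 0 mM neurospheres.

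Product appeared earlier in neurospheres exposed to 100 mM ethanol. The mean cycle number over the 50 widely detected assays was 13.9 ± 2.20 cycles at 0 mM (SD, n = 68) and 11.5 ± 1.94 at 100 mM (SD, n = 66). Within run and set the difference was -2.43 cycles (SE 0.34, adjusted p = 3e-05, permutation test), and it was negative in 4 of 4 combinations of run and set. At 70 mM the difference was -0.86 cycles (SE 0.40, adjusted p = 0.0655), which did not pass; it was -2.09 in run 1 alone (adjusted p = 0.00397), which passed, and -0.27 in runs 2 and 3 alone (adjusted p = 0.619). At 25 mM it was 0.41 cycles (SE 0.36, adjusted p = 0.256). The culture sets differed in this response. In Set-B the differences were -2.50 cycles at 70 mM (SE 0.49) and -3.48 at 100 mM (SE 0.48), while in Set-A they were 0.77 (SE 0.63) and -1.39 (SE 0.48). The difference between sets passed at 70 mM (adjusted p = 0.00066) and at 100 mM (adjusted p = 0.00578), by permutation after removal of the pooled dose difference. Within combinations, the 100 mM difference was -0.26 cycles in run 1 Set-A, -1.94 in run 2 Set-A, -3.60 in run 1 Set-B and -3.41 in run 3 Set-B.

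**Figure D1:**
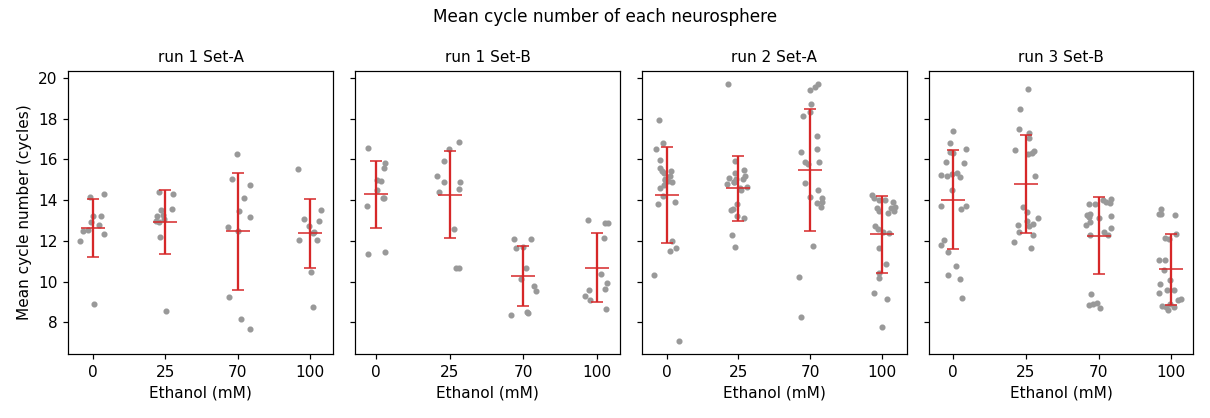
Mean cycle number of each neurosphere (vertical axis, cycles) by ethanol dose (horizontal axis, mM) in the 4 combinations of run and set. Grey points are neurospheres and red marks are means with SD bars; in run 1 Set-B the mean was 14.3 cycles at 0 mM and 10.7 at 100 mM, against 12.6 and 12.4 in run 1 Set-A.

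The normalization removes this overall difference, so the following changes are relative to the mean of the widely detected assays. Without normalization the median assay moved by -0.52 on the log2 scale at 25 mM, by 0.87 at 70 mM and by 2.27 at 100 mM. At 70 mM the median assay moved by -0.72 in Set-A and 2.28 in Set-B, and at 100 mM the values were 1.19 and 3.30. The direction of Set-A at 70 mM is not settled. Its mean cycle difference was 0.77 (SE 0.63), with -0.16 in run 1 Set-A and 1.23 in run 2 Set-A.

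At 25 mM, 18 of 72 assays changed relative to 0 mM, 7 higher and 11 lower (limma, adjusted p under 0.05). The median size among them was 2.08-fold, and 16 of the 18 had the same direction in both culture sets. These 18 were chosen in a fit of both sets; of all 72 assays, 29 had the same direction. Set-A alone called 23 assays, Set-B alone 30 and run 1 alone 11. A025 was 3.98-fold higher (log2 change 1.99, SE 0.28, adjusted p = 5.77e-10) and was higher in 4 of 4 combinations of run and set. A045 fell by 2.51 on the log2 scale (SE 0.89, adjusted p = 0.0242), with -2.97 in Set-A (SE 0.86) and 6.40 in Set-B (SE 4.99). It was detected in 0 of the 88 neurospheres of run 3, so its Set-B values come from 24 neurospheres of run 1. Few of these 24 were at 0 mM, so the Set-B values of A045 do not settle a direction. With missing values set to 30 cycles, its level in run 3 was the neurosphere's mean cycle number minus 30. At each dose that setting therefore mixes the mean cycle difference of run 3 into the change of A045. A058 and A009 did not pass, with log2 changes of -0.29 (SE 0.32) and -0.47 (SE 0.27). A058 was 0.82 in Set-A (adjusted p = 0.0612) and -1.59 in Set-B (adjusted p = 0.000679). A009 passed in Set-A alone (-1.06, adjusted p = 0.0425), without normalization (-0.85, adjusted p = 0.0387) and with mean cycle number as a covariate (-0.65, adjusted p = 0.00522). The A025 call ended without normalization (1.55, adjusted p = 0.0651), and the A045 call ended with missing values set to 30 cycles (-0.41, adjusted p = 0.745), with diameter as a covariate (-1.998, SE 0.96, adjusted p = 0.131) and on the 5 steadiest assays (-1.92, adjusted p = 0.0599). It also ended without run 1, where its values come from run 2 Set-A (-1.36, SE 0.72, adjusted p = 0.199), and, with a larger change, in run 1 alone (-4.48, SE 1.80, adjusted p = 0.0844). Without normalization 0 assays were higher and 8 lower, and centring on the 5 steadiest assays, a choice made after seeing the data, gave 8 higher and 6 lower. With 1 mean per culture set and dose, 8 means in all, limma called 0 assays, and 2 had an unadjusted p under 0.05. A025 was 2.14 (SE 0.96) in that fit. A045 was -3.70 there, from Set-A means alone, because it had no Set-B mean.

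At 70 mM, 44 of 72 assays changed, 21 higher and 23 lower, by a median of 2.27-fold. The direction was the same in both culture sets for 41 of the 44, against 54 of all 72, and in all 4 combinations of run and set for 28. Set-A alone called 24 assays and Set-B alone 51. A025 was 10.9-fold higher (log2 change 3.45, SE 0.28, adjusted p = 1.32e-26), with 2.18 in Set-A (SE 0.32) and 4.75 in Set-B (SE 0.34). A058 rose by a log2 change of 1.25 (SE 0.31, adjusted p = 0.000189), with 0.25 in Set-A (SE 0.35) and 2.34 in Set-B (SE 0.39). A009 fell by 1.79 (SE 0.27, adjusted p = 3.38e-09), with -1.58 in Set-A and -1.97 in Set-B. A045 fell by 3.69 (SE 0.90, adjusted p = 0.000164), with -3.95 in Set-A and -0.12 in Set-B (SE 4.27). The A058 call ended in Set-A alone (adjusted p = 0.644), the A009 call without normalization (-0.54, adjusted p = 0.116) and the A045 call with missing values set to 30 cycles (-1.44, adjusted p = 0.097) and without run 1, that is in run 2 Set-A (-1.40, adjusted p = 0.127), against -6.12 in run 1 alone (adjusted p = 0.00249). A009 was -0.43 on the 5 steadiest assays and -1.17 with mean cycle number as a covariate. A058 was 1.89 without normalization, 2.10 on the 5 steadiest assays and 2.01 with missing values set to 30 cycles. These A009 and A058 changes passed. Other scalings moved the split: 28 higher and 20 lower with the median in place of the mean, 23 and 2 without normalization, and 40 and 5 on the 5 steadiest assays. Without normalization the split was 0 higher and 8 lower in Set-A, and 52 and 0 in Set-B. The fit of 1 mean per culture set and dose called 0 assays in limma, with 7 at an unadjusted p under 0.05. In it A025 was 3.63 (adjusted p = 0.0582), A009 was -1.92 (adjusted p = 0.394) and A058 1.29 (adjusted p = 0.535). Each of these 3 was at least as large as in the fit of single neurospheres. A045 was -4.63 there, from Set-A means alone, because it had no Set-B mean.

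At 100 mM, 45 of 72 assays changed, 22 higher and 23 lower, by a median of 1.99-fold. Here 28 of the 45 had the same direction in both culture sets, against 36 of all 72, and 12 in all 4 combinations of run and set. A025 was 4.80-fold higher (log2 change 2.26, SE 0.28, adjusted p = 3.76e-13), and the change was 0.19 in Set-A (SE 0.32) and 4.36 in Set-B (SE 0.34). A058 was 3.45-fold higher (log2 change 1.79, SE 0.31, adjusted p = 2.63e-07), with 0.55 in Set-A (SE 0.35) and 3.09 in Set-B (SE 0.39). A009 fell by 1.68 (SE 0.27, adjusted p = 2.42e-08), with -0.71 in Set-A (SE 0.42) and -2.62 in Set-B (SE 0.29); without normalization it was higher by 0.70, and with missing values set to 30 cycles it was -0.78 (adjusted p = 0.131). With mean cycle number as a covariate it was -0.50 (adjusted p = 0.0549), and on the 5 steadiest assays -0.35 (adjusted p = 0.00903). Without normalization A025 was 4.66 and A058 was 3.999, on the 5 steadiest assays they were 3.54 and 2.97, and A025 was 1.37 with mean cycle number as a covariate; these passed. In Set-A alone none of these 3 assays passed in limma, with adjusted p of 0.736 for A025, 0.281 for A058 and 0.254 for A009. A045 fell by 2.09 (SE 0.86, adjusted p = 0.0299), a value among neurospheres that detected it, with -1.80 in Set-A (adjusted p = 0.147) and -0.12 in Set-B (SE 4.25, adjusted p = 0.978). The Set-B value of A045 rests on few 0 mM neurospheres, so its same direction in both sets carries little weight. With missing values set to 30 cycles its change was 0.07, in a fit to which run 3 contributed mean cycle number alone. The A045 call also ended without normalization (-0.48, adjusted p = 0.498), with mean cycle number as a covariate (-0.37, adjusted p = 0.76), on the 5 steadiest assays (-1.20, adjusted p = 0.129), with diameter as a covariate (-1.72, adjusted p = 0.0885), in run 1 alone (-2.55, adjusted p = 0.2) and in a fit of the 0 and 100 mM neurospheres alone (-1.68, adjusted p = 0.0502). Set-A alone gave 9 changed assays, Set-B alone 54 and run 1 alone 27. Without normalization 67 assays were higher and 0 lower, and on the 5 steadiest assays 52 were higher and 1 lower. The median assay moved by 1.31 on the log2 scale on the 5 steadiest assays, against 2.27 without normalization. That scaling thus left much of the overall difference in. With mean cycle number as a covariate, a fit added after seeing the data, 22 assays passed, and with 1 mean per culture set and dose limma called 0, with 3 at an unadjusted p under 0.05. In that fit of 8 means A025 was 2.34 (SE 0.96), A058 1.88 (SE 0.96) and A009 -1.66 (SE 0.84). A045 was -1.55 there, from Set-A means alone, because it had no Set-B mean.

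Across the 72 assays, the log2 changes of the culture sets were compared with each other, each set against its own 0 mM neurospheres. Pearson's r was -0.25 at 25 mM, 0.38 at 70 mM and -0.15 at 100 mM, and 29, 54 and 36 of 72 assays had the same sign. Spearman's rho was -0.10, 0.48 and -0.05. The values include A045, whose Set-B change does not settle a direction. Between the 2 runs of Set-B, r was 0.41, 0.67 and 0.70 over 70 assays. Between the 2 runs of Set-A, r was 0.54, 0.41 and 0.19 over 72 assays. Assays are not independent replicates, and no p-value is given for these values.

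**Figure D2:**
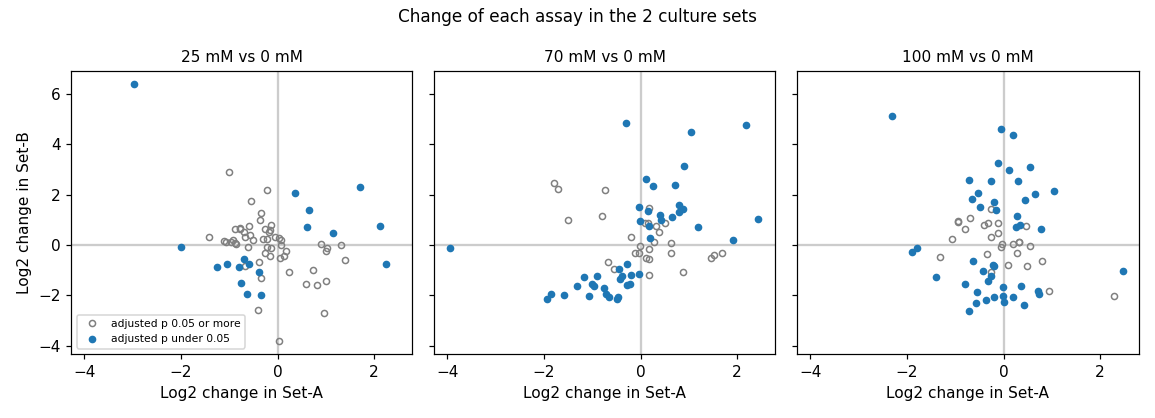
Log2 change of each of 72 assays against 0 mM in Set-A (horizontal axis) and Set-B (vertical axis) at 25, 70 and 100 mM ethanol. Filled points have adjusted p under 0.05 in the fit of both sets; r was -0.25, 0.38 and -0.15.

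The ethanol doses also differed from each other. Between 70 and 25 mM, 48 assays differed, 26 higher and 22 lower at 70 mM. Between 100 and 25 mM, 43 differed, 22 higher and 21 lower at 100 mM. Between 100 and 70 mM, 19 differed, 10 higher and 9 lower at 100 mM. A025 was lower at 100 than at 70 mM by a log2 change of -1.19 (SE 0.28, adjusted p = 0.000299), which was 0.37 without normalization (adjusted p = 0.553), -0.83 on the 5 steadiest assays (adjusted p = 0.227) and -0.39 in Set-B alone (adjusted p = 0.805). A009 did not pass (0.11, SE 0.27) but did without normalization (1.24, adjusted p = 9.18e-05) and with mean cycle number as a covariate (0.67, adjusted p = 0.00313). In Set-A A009 was 0.87 and in Set-B -0.66, and neither passed. Without normalization the splits were 42 higher and 2 lower, 69 and 0, and 51 and 0; on the 5 steadiest assays they were 39 and 7, 46 and 2, and 13 and 0. With the median, the split between 100 and 70 mM was 8 higher and 16 lower. Set-A alone called 31 assays and Set-B alone 46 between 70 and 25 mM, and 9 and 50 between 100 and 25 mM. Between 100 and 70 mM, 37 assays differed in Set-A alone, and in Set-B alone limma called 0 with 9 at an unadjusted p under 0.05. That contrast had 2 assays in run 1 alone and 41 with mean cycle number as a covariate. With 1 mean per culture set and dose, limma called 0 assays in each of these 3 contrasts, with 11, 5 and 1 at an unadjusted p under 0.05.

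A linear trend over dose was found in 51 of 72 assays, 27 rising and 24 falling. A025 rose by 2.38 log2 units per 100 mM (SE 0.28, adjusted p = 6.22e-14), A058 rose by 2.07 (SE 0.29, adjusted p = 5.8e-11) and A009 fell by 1.86 (SE 0.25, adjusted p = 9.03e-12). A045, among neurospheres that detected it, was lowest at 70 mM. With run and set means removed its levels were 2.01, -0.48, -1.49 and 0.08 at 0, 25, 70 and 100 mM. Set-B alone gave 56 assays and Set-A alone 2. A025 had a slope of 0.29 in Set-A (SE 0.36) and 4.49 in Set-B (SE 0.35), and in Set-A alone A025, A058 (0.25, adjusted p = 0.703) and A009 (-0.67, adjusted p = 0.333) did not pass. The slopes of A025 and A058 were 4.88 and 4.36 without normalization and 3.73 and 3.34 on the 5 steadiest assays. A009 was -0.36 on the 5 steadiest assays and -0.62 with mean cycle number as a covariate, and each of these slopes passed. Without normalization 68 assays rose and 0 fell, A009 among those that rose with 0.77, and on the 5 steadiest assays 52 rose and 1 fell. With mean cycle number as a covariate 32 assays passed, 15 rising and 17 falling. The fit of 1 mean per culture set and dose called 0 assays in limma, with 13 at an unadjusted p under 0.05, and its slopes were 2.42 for A025 (SE 1.17), 2.15 for A058 (SE 0.89) and -1.90 for A009 (SE 0.70).

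Of 25 assays detected in 5% to 95% of neurospheres, 21 changed their detection share at 100 mM, 20 upward and 1 downward (exact conditional Mantel-Haenszel test). At 70 mM 7 changed, all upward, and at 25 mM 5 changed, 1 upward and 4 downward. With values above 25 cycles read as not detected, 20 rose and 0 fell at 100 mM. In that setting 6 rose and 0 fell at 70 mM, and 0 rose and 4 fell at 25 mM. A045 was detected in 44 of 66 neurospheres at 100 mM and in 33 of 68 at 0 mM (adjusted p = 5.2e-05), although its level among detecting neurospheres was lower. Over all doses it was detected in 100.0% of run 1 Set-A, 54.5% of run 1 Set-B, 89.8% of run 2 Set-A and 0.0% of run 3 Set-B. Its difference between doses thus comes from run 1 Set-B and run 2 Set-A, the latter near its ceiling. Mean cycle number at 100 mM fell by 2.43 cycles. Set-A alone gave 4 assays at 100 mM, 1 at 70 mM and 7 at 25 mM, and Set-B alone gave 23, 19 and 1.

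Neurospheres were smaller in all 3 ethanol groups. The mean diameter was 55.8 ± 31.9 micrometres at 0 mM (SD, n = 68), 39.1 ± 11.5 at 25 mM (n = 64), 41.01 ± 13.7 at 70 mM (n = 66) and 37.5 ± 14.5 at 100 mM (n = 66). On the log2 scale the differences from 0 mM were -0.42 (SE 0.09, adjusted p = 3e-05), -0.35 (SE 0.09, adjusted p = 0.00037) and -0.51 (SE 0.09, adjusted p = 3e-05; permutation tests), and each was negative in 4 of 4 combinations of run and set. The 22 diameters at 100 mM in run 3 Set-B were not multiples of the step of 0.346 micrometres that the other 242 diameters shared within 0.001 micrometres, and whether they are on the same scale is not given in the sources used here. That combination gave -0.71 at 100 mM and run 1 Set-B gave -0.13; without run 3 Set-B, left out after seeing the data, the differences were -0.56, -0.47 and -0.40 (adjusted p = 0.00012, 0.000765 and 0.0027). Over all combinations the values are ratios of geometric means of 0.748, 0.782 and 0.704 at 25, 70 and 100 mM. The size of the difference depended on the set at 25 mM (adjusted p = 0.00414) and at 70 mM (adjusted p = 0.019). In Set-A the difference was -0.71 at 25 mM and -0.60 at 70 mM. In Set-B it was -0.12 (SE 0.10) and -0.11 (SE 0.10), neither of which passed. At 100 mM it was -0.49 in Set-A and -0.52 in Set-B, and the difference between sets did not pass (-0.02, adjusted p = 0.964). That Set-B value rests on the 22 diameters of run 3 that lie off the common step, since run 1 Set-B gave -0.13. The likeness of the sets at 100 mM therefore depends on those diameters. The 0 mM neurospheres of run 1 Set-A had a mean of 86.2 micrometres, while the ethanol groups of that combination lay between 40.5 and 43.7. How neurospheres were picked for measurement is not given in the sources used here.

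**Figure D3:**
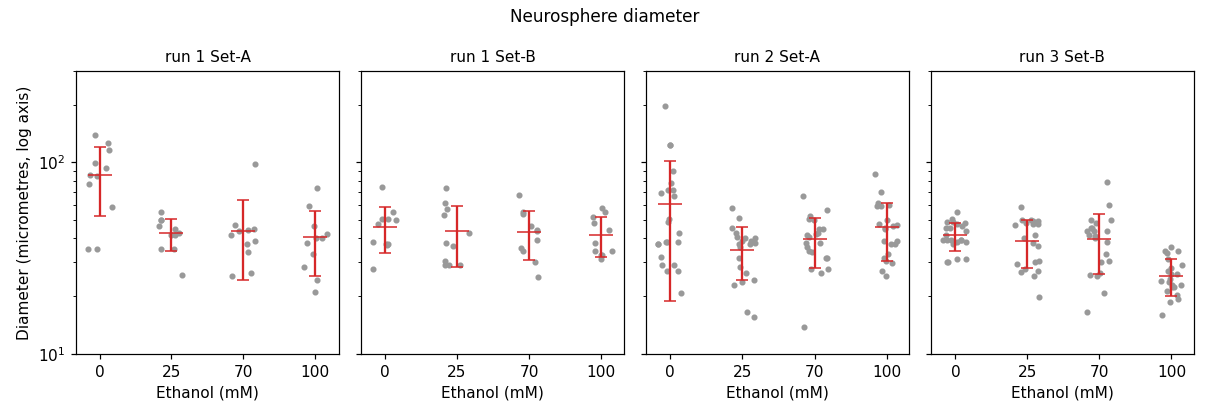
Diameter of each neurosphere (vertical axis, micrometres, log scale) by ethanol dose (horizontal axis, mM) in the 4 combinations of run and set. Grey points are neurospheres and red marks are means with SD bars; the mean at 0 mM was 86.2 micrometres in run 1 Set-A and 41.5 in run 3 Set-B, where it was 25.6 at 100 mM on diameters off the step shared by the others.

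Diameter was related to the relative level of 14 of 72 assays, 9 higher and 5 lower in larger neurospheres, with dose, run and set in the model. The median size was a 1.35-fold change per doubling of the diameter. A025, A058, A045 and A009 did not pass, with slopes of 0.39 (SE 0.19), -0.31 (SE 0.21), 0.75 (SE 0.55) and 0.27 (SE 0.19); without normalization A009 passed with 0.61 (adjusted p = 0.0407). Without the 22 neurospheres at 100 mM in run 3 Set-B, 25 assays passed, 13 higher and 12 lower, A025 among them with 0.65 (SE 0.20, adjusted p = 0.00752). With size group in place of diameter 4 assays passed, 3 higher and 1 lower. Set-A alone gave 13 assays; Set-B alone gave 0 in limma, with 26 at an unadjusted p under 0.05. The split was 9 higher and 2 lower with the median, 3 and 0 without normalization, and 1 and 5 on the 5 steadiest assays. The test of whether the response to dose depended on diameter called 28 of 72 assays (F test of the interaction), A025 (adjusted p = 0.000418) and A058 (adjusted p = 0.0329) among them. This count rested on the 22 neurospheres at 100 mM in run 3 Set-B: without them 1 assay passed, with 15 at an unadjusted p under 0.05, and A025 (adjusted p = 0.47) and A058 (adjusted p = 0.581) did not. Without normalization 6 assays passed, and on the 5 steadiest assays 3, with adjusted p of 0.0782 for A025 and 0.175 for A058. The A058 call also ended without normalization (adjusted p = 0.0531), with missing values set to 30 cycles (adjusted p = 0.436) and on the rank scale (adjusted p = 0.162).

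No relation of mean cycle number to diameter passed. The correlations took no account of dose, and at 100 mM both values were lower, which moves r upward and can hide a negative relation. Over 264 neurospheres Pearson's r was 0.011 (permutation p = 0.841, adjusted p = 0.989) and Spearman's rho was 0.003 (permutation p = 0.952, adjusted p = 0.997), among 7 relations tested. Without the 2 neurospheres farthest from the median diameter r was -0.001. Within run 1 Set-A, run 1 Set-B, run 2 Set-A and run 3 Set-B, r was -0.024, -0.002, -0.041 and 0.115. Without the 22 neurospheres at 100 mM in run 3 Set-B r was -0.111 (permutation p = 0.106, adjusted p = 0.742) and rho -0.13 (permutation p = 0.0561, adjusted p = 0.393). With dose, run and set in the model, the slope was -0.35 cycles per doubling of the diameter (95% confidence interval -0.88 to 0.18), and without those 22 it was -0.49 (-1.05 to 0.07).

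Culture sets were compared in run 1, which held both. With dose in the model, 28 of 72 assays differed, 16 higher and 12 lower in Set-B. A058 was lower in Set-B by a log2 change of -1.67 (SE 0.33, adjusted p = 4.34e-05), a call that ended without normalization (-1.07, adjusted p = 0.317) and on the 5 steadiest assays (-1.26, adjusted p = 0.0647), and A025 (0.33, SE 0.34) and A009 (0.12, SE 0.35) did not pass. The split was 10 higher and 12 lower with the median, 4 and 1 without normalization, 9 and 4 on the 5 steadiest assays and 8 and 10 with missing values set to 30 cycles. The response to dose differed between the culture sets for 59 of 72 assays (F test of the interaction), including A058 (adjusted p = 3.49e-18), A025 (adjusted p = 1.16e-16) and A009 (adjusted p = 1.7e-07) but not A045 (adjusted p = 0.0581, and 0.00109 without normalization).

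The main axis of variation among neurospheres took 35.1% of the variance of the 72 relative levels after run and set means were removed. Its sign was set so that higher scores go with lower mean cycle numbers (r = -0.613 across neurospheres). The scores thus still followed the overall signal after centring, and no test of them took account of mean cycle number. Their differences between doses may partly repeat the difference in mean cycle number. Scores were higher than at 0 mM by 0.62 at 70 mM (SE 0.08, adjusted p = 3e-05) and by 0.41 at 100 mM (SE 0.09, adjusted p = 9e-05), and differed by -0.10 at 25 mM (SE 0.08, adjusted p = 0.228; permutation tests). At 70 mM the difference was 0.36 in Set-A and 0.87 in Set-B, and positive in 4 of 4 combinations of run and set, and at 100 mM in 2 of 4. In Set-A the 100 mM difference was -0.10 (SE 0.13) and in Set-B 0.93 (SE 0.12), which differed from each other (adjusted p = 0.00012). The mean cycle differences in Set-A were 0.77 cycles (SE 0.63) at 70 mM and -1.39 (SE 0.48) at 100 mM. The score differences of that set did not follow them. The spread of scores around the median of their run, set and dose, tested after seeing the data, was 0.439 at 0 mM and narrower by 0.176 at 25 mM, 0.144 at 70 mM and 0.129 at 100 mM (adjusted p = 0.00207, 0.00894 and 0.0224). In Set-A alone the difference in spread was 0.02 at 70 mM and -0.03 at 100 mM, and neither passed. With diameter regressed out the differences at 70 and 100 mM kept their direction at -0.10 and -0.10, with adjusted p = 0.0734 for both, and within run 1 none of the 3 passed.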

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

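The tests of neurosphere size, single runs, culture differences, run template and exchanged labels below, the counts over other splits, the fit without the 100 mM neurospheres of run 3 Set-B and the spread of scores were chosen after the results were seen; the overall signal test was fixed before its result, after the counts with mean cycle number as covariate.

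The responses of Set-A and Set-B to ethanol differed by tests of the difference itself, for 59 of 72 assays and for several single values. Set-B minus Set-A, the log2 diameter response differed by 0.592 at 25 mM and 0.483 at 70 mM. The mean cycle number response differed by -3.272 cycles at 70 mM and -2.088 at 100 mM. The score response on the main axis differed by 0.502 at 70 mM and 1.034 at 100 mM, and the response of its spread by -0.323 at 70 mM. Among the named assays the interaction had adjusted p = 1.7e-07 for A009, 1.16e-16 for A025 and 3.49e-18 for A058.

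The earlier appearance of product at 70 and 100 mM in Set-B was weighed against 3 explanations. Neurosphere size is argued against because the log2 diameter differences were -0.11 at 70 mM in Set-B and -0.13 at 100 mM in run 1 Set-B, and with the slope on diameter their intervals allow at most -0.18 cycles, where -2.50 and -3.60 were measured, with intervals that end at -1.55 and -2.20. A single measurement run would show it in 1 run, but the difference nearest 0 among both runs and both doses was -1.76 cycles, with an interval from -3.03 to -0.49. Culture differences unrelated to dose stay open: 7 of the 24 ways to assign the 4 Set-B mean cycle numbers to doses, the real one included, correlated with those of Set-A at least as well as the real one (r = 0.492), and the labels tie no neurosphere to 1 of the 6 isolations. An ethanol response that differs between cultures, and a difference between cultures that was not caused by ethanol, cannot be told apart here.

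Several assays were detected many cycles later in runs 2 and 3 than in run 1. Of 7 that moved later by over 5 cycles, with low detection counted as 30 cycles, 4 were detected in most neurospheres of both and moved by 8.0 to 12.7 cycles. A024 and A045 are among the 7 only because run 3 Set-B did not detect them. Run 2 Set-A detected them in 81.8% and 89.8% of neurospheres. Their median cycles there were 19.01 and 19.61, against 17.49 and 16.72 in run 1 Set-A. Less template in runs 2 and 3 is argued against by the other 67 assays, whose median shift was 0.07 cycles. Labels exchanged among the assays analysed would need partners, and 1 assay moved over 5 cycles the opposite way, so an exchange involving that assay or assays not analysed here remains possible and may account for part of the pattern. No biological explanation was tested, since runs are not a group of the design.

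The assay changes at 100 mM may partly follow each assay's dependence on the overall signal, as a hypothesis. The slope of each relative level on mean cycle number, taken in the 64 neurospheres at 25 mM, gave an expected change that correlated with the measured change across 72 assays with r = 0.45 (95% bootstrap interval over assays 0.19 to 0.66). The value lies between the bounds set before the test, so it leaves the explanation open, and assays are not independent. An ethanol effect on these transcripts is also open.

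Other splits, 100 for each result with the real one included, permuted dose labels within run and set, or diameters or set labels where those were compared. Taken 1 at a time, chance assignment of neurospheres could be excluded at a share of 0.05 where 1 of 100 splits, the real one, gave as many assays. For the dose by diameter interaction 2 of 100 splits did, and another split called 39 assays against the real 28; with the 22 at 100 mM in run 3 Set-B left out, 1 assay passed. The real count and the highest of the other splits were 18 and 17 at 25 mM, 44 and 1 at 70 mM, 45 and 2 at 100 mM, 48 and 20 for 70 against 25 mM, 43 and 7 for 100 against 25 mM, and 19 and 3 for 100 against 70 mM. They were 51 and 4 for the trend, 14 and 5 for diameter, 28 and 7 for the culture sets, 59 and 1 for dose by set, and 28 and 39 for dose by diameter. For detection they were 5 and 2 at 25 mM, 7 and 0 at 70 mM, and 21 and 2 at 100 mM. These splits exchange neurospheres and say nothing about chance differences between cultures.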

How the results depend on the processing

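The 5 steadiest assays, the mean cycle covariate, the spread of scores, a normalization set without assays that shift between runs, runs 2 and 3 alone, and the fits without run 3 Set-B or its 100 mM neurospheres were chosen after seeing the data. Of 248 comparisons of a main result with an alternative, 195 kept their direction and side of the threshold, or stayed within 1.5 times the count, and in 17 of these the split of higher and lower calls still moved by over 10 points. For the 4 named assays it was 167 of 213, with 34 weaker, 4 stronger and 8 reversed. The cause of the moves below was not tested, except that smaller fits hold fewer neurospheres. Keeping all neurospheres is not counted, because the filter removed 0. Reference gene normalization, the reference gene mean cycle number, gene list scores and the maturation score were not run.

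With 1 mean per culture set and dose, limma called 0 assays in each dose contrast and in the trend, on 8 means, with 1 to 13 at an unadjusted p under 0.05. The changes of A025, A058 and A009 behind lost calls against 0 mM stayed about as large or grew (A025 at 70 mM 3.63, adjusted p = 0.0582). A045 had no Set-B mean in that fit, so its values, such as -1.55 at 100 mM, are from Set-A alone. Set-A alone gave 24 assays at 70 mM, 9 at 100 mM, 31 for 70 against 25 mM, 9 for 100 against 25 mM, 37 for 100 against 70 mM and 2 for the trend; detection gave 1 at 70 mM and 4 at 100 mM. There the 70 mM mean cycle difference was 0.77, the 100 mM score difference -0.10, the spread differences 0.02 at 70 mM and -0.03 at 100 mM, and A058 at 25 mM 0.82. Set-B alone gave 30 at 25 mM, and in limma 0 for 100 against 70 mM and 0 for diameter, with 9 and 26 at an unadjusted p under 0.05; detection gave 1 at 25 mM and 19 at 70 mM. There diameter differences were -0.12 at 25 mM and -0.11 at 70 mM, the 70 mM mean cycle difference -2.50, A009 at 25 mM 0.13 and A045 at 25 mM 6.40. Run 1 alone gave 11 at 25 mM, 27 at 100 mM and 2 for 100 against 70 mM, a 70 mM mean cycle difference of -2.09, spread differences of -0.09, -0.05 and -0.09, and A058 at 25 mM at 0.06.

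Without normalization the counts were 8 at 25 mM, 25 at 70 mM, 69 for 100 against 25 mM, 51 for 100 against 70 mM, 3 for diameter, 5 for culture sets and 6 for dose by diameter, and A009 at 100 mM was 0.70. The 5 steadiest assays gave 6 for diameter, 13 for culture sets and 3 for dose by diameter. Mean cycle number as covariate gave 22 at 100 mM, 41 for 100 against 70 mM and 32 for the trend. Non-detects at 30 cycles gave 18 for culture sets, A009 at 25 mM 0.43 and A045 at 100 mM 0.07. On the rank scale A058 at 25 mM was 0.00. With size group in place of diameter, 4 assays were related to it, against 14. Without the 100 mM neurospheres of run 3 Set-B, 25 assays were related to diameter and 1 had a dose by diameter interaction. With diameter regressed out the spread differences were -0.10 at 70 mM and -0.10 at 100 mM.

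The well label as a replicate block gave 16, 44 and 43 assays at 25, 70 and 100 mM and 50 for the trend. Wells did not pair neurospheres: deviations of the same well correlated at a mean r of 0.005 over 390 pairs, with 152 pairs over 0.1, against 0.003 for other wells, of which 40.9% were over 0.1.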

Other observations

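The tests in this part were chosen after the results were seen.

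The cycle numbers of the 50 widely detected assays varied together before normalization. Their main axis took 78.0% of the variance after run and set means were removed, with the same sign for 50 of 50 assays. The assays followed it to different degrees, with SDs from 1.49 to 4.04 cycles.

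Template that followed the volume of a sphere would lower the mean cycle number by 3 cycles per doubling of the diameter. The measured slope was -0.35 cycles with a 95% confidence interval from -0.88 to 0.18, and without the 22 neurospheres whose diameters lay off the common step it was -0.49 with an interval from -1.05 to 0.07; both exclude that value. At 100 mM, the number of detected assays per neurosphere was 70.8 ± 2.20 (SD, n = 66) against 65.8 ± 5.60 at 0 mM (SD, n = 68), while the mean diameter was lower. The means were 71.5 against 62.97 in Set-B, 70.1 against 68.6 in Set-A, and 70.8 against 70.0 in run 1 Set-A, and these differences were not tested.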
